A study of Homo sapiens with 6 samples.

How the data were processed

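Total RNA of A375 melanoma cells was profiled 3 days after siRNA transfection on 6 Affymetrix Clariom S Pico human arrays, 3 for the control siRNA and 3 for the siRNA against ERK3. Per the labels' protocols, the siRNAs were predesigned commercial reagents delivered with a commercial transfection reagent, RNA was extracted with Trizol, samples passed a minimum RNA integrity number, and the WT PLUS kit was used for 1-colour biotin labelling. The sequence of the siRNA is not given in the sources used here, so transcripts that share its seed were not tested.

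The values analysed are those the authors deposited, 1 log2 value per probe set and array. The log2 scale was read from the values themselves, whose lowest lies between 1.84 and 2.09 and whose highest between 19.1 and 19.4 on the 6 arrays. The software, background correction, summarisation and normalization are not given in the sources used here. Array medians over all probe sets lie between 7.06 and 7.10, so some normalization between arrays was applied before the values were deposited. Between 1.46% and 1.61% of the probe sets exceed 16, the log2 limit of a 16-bit scanner, so the zero point of the scale stays unknown. Whether the scale is also stretched is unknown too. Differences between arrays do not depend on a zero point, but they and the folds given here would depend on a stretch. No gene was centred.

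The platform annotation gave exactly 1 gene symbol for 17709 of the 24351 probe sets and several for 0. The others were 3739 probe sets unnamed in it, 612 negative controls, 2197 positive controls and 94 spike-in or background controls, which stayed out of the gene test. For 20 genes with more than 1 probe set the brightest by mean over all 6 arrays was taken, which left 17687 genes. Symbols were compared with a RefSeq gene table through Entrez identifiers, and 0 needed an update. No filter on low values and no pseudocount were applied. Genes missing from the annotation used were not analysed here.

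The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, siERK3 minus siCon, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors and 95% intervals are those of the moderated fit, whose prior had 4.77 degrees of freedom; the median standard error of a gene was 0.165 on the log2 scale. The number of arrays limits the precision. MAPK6 was also tested with an exact two-sided permutation test. The table of values used holds no detection calls, so the 95th percentile of the 612 negative controls on each array served as the background level. A gene at or below that level on all 3 arrays of a group is called below it in that group. Its change is given as a bound, "at least N-fold", computed against the higher of that level and the gene's own value on each array, and as log2 levels where both groups were below it or the bound was under 1; where only some arrays of a group lay above it, their number is given.

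Before the data were examined, 33 gene lists with 928 entries (823 measured) were fixed, on ERK signalling, melanoma states, cell cycle, inflammation, stress, metabolism, matrix and markers of other cell types, with MAPK6 in none. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes and adjusted over the 33 lists; the result of 1 list that camera did not call is not reported here. The genes named were also fixed by a rule beforehand, the naming rule. It takes MAPK6, the 10 largest rises and the 10 largest falls among genes past the threshold with no overlap between groups, and up to 3 members with the smallest p from each list that camera called or that held at least 3 members past the threshold. Other genes were named after their values were seen.

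Alternatives fixed beforehand were quantile normalization, subtraction of each array's median, cyclic loess, filters at the 30th percentile and at the median of mean level, all probe sets tested, the mean of a gene's probe sets, a mean-variance trend with robust eBayes, array weights, no moderation of the variance, the replicate number as a block, each array left out in turn, and for the lists an estimated correlation, fry and ranks. The unnamed and control probe sets were examined as an alternative added after seeing the data, as were the shares of each kind of probe set whose groups did not overlap.

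The scripts were tested on simulated data, 20 simulations with 200 changed genes each among 17687. Values were drawn from a normal distribution with the real genes' siCon means and the spread after limma's moderation. That spread varies less between genes than the observed one, so the shares below may be too favourable for the real data. They recovered 63.9% of genes changed by 0.8 on the log2 scale, 97.2% at 1.2, 99.9% at 1.6 and all at 2, with 5.72% false calls. A list shifted by 0.3 was found in 20 of 20 simulations, with 0 other lists called. The lists that camera called in the real data moved less than that, except the cytokine list, so recovery of such smaller shifts was not tested. Each gene was simulated independently of the others, so false list calls that arise from correlation between genes could not appear. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15 from the tables of results.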

Results

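Gene expression was measured in A375, an established human melanoma cell line, 3 days after transfection with a small interfering RNA (siRNA) against ERK3 (siERK3) or with a negative control siRNA (siCon). ERK3 is an atypical mitogen-activated protein kinase encoded by MAPK6. Each group had 3 arrays, and each array gave a log2 value for 24351 probe sets, from which 17687 genes were compared. Array medians lay between 7.06 and 7.10, and between 45.6% and 47.6% of the genes lay above the 95th percentile of the negative controls of the same array. Across genes, which are not independent replicates, Pearson's r was 0.992 to 0.995 within siCon, 0.994 to 0.995 within siERK3 and 0.991 to 0.993 between the groups. On the second principal component, siCon 2 at -26.5 and siERK3 3 at -15.2 stood apart from the other 4 arrays, which lay between 4.35 and 21.7. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

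The comparison asks which transcripts differ after ERK3 knockdown, and the target was examined first. MAPK6 (probe set TC1500010743.hg.1) averaged 13.54 ± 0.09 (SD, n = 3) in siCon and 10.51 ± 0.18 (SD, n = 3) in siERK3 on the log2 scale. Its signal fell 8.18-fold, to 12.2% of the control signal (95% confidence interval 9.77% to 15.3%). The log2 change of -3.03 (SE 0.14) had an adjusted p of 0.000133 in limma and ranked 1 among all genes by p. The exact two-sided permutation test of the 6 values gave p = 0.1, the smallest p that 3 against 3 arrays allow. All 3 siERK3 arrays lay below all 3 siCon arrays.

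After ERK3 knockdown, 169 genes passed limma's test with Benjamini-Hochberg adjustment, 79 of them higher and 90 lower in siERK3. MGP, which encodes matrix Gla protein, a secreted inhibitor of calcification, rose 7.82-fold, from 8.43 ± 0.39 to 11.40 ± 0.20 (log2, SD, n = 3 each). CHPF, an enzyme of chondroitin chain synthesis, rose 4.28-fold, EMP2, a membrane protein of the tetraspan type, rose 3.20-fold, and L1CAM, a cell adhesion molecule, rose 3.07-fold. In the other direction, PTX3, a secreted pentraxin of innate immunity, fell 4.47-fold, from 10.44 ± 0.16 to 8.27 ± 0.16. LIMK1, the kinase that phosphorylates cofilin, fell 3.25-fold, and NT5E, the ectonucleotidase that forms adenosine, fell 2.99-fold, from 14.65 ± 0.09 to 13.07 ± 0.26.

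Among the 10 largest rises, A2M, a broad protease inhibitor, was at least 3.65-fold higher in siERK3, its siCon level of 7.16 lying below the negative controls' 95th percentile on all 3 arrays. The rises of CNIH2, YWHAH (a 14-3-3 protein) and IL10RB (a cytokine receptor subunit) were 3.15-fold, 2.91-fold and 2.65-fold. In siCon, CHPF and IL10RB lay above the negative controls' 95th percentile on 2 of 3 arrays each. FAIM2 rose from 5.39 to 7.21 and IL1RL1, a receptor of the IL-1 family, from 4.87 to 6.67 on the log2 scale, with no fold given for either. FAIM2 lay above the negative controls' 95th percentile on 0 siCon arrays and 1 siERK3 array, and IL1RL1 on 0 arrays of both groups. Among the 10 largest falls, PLEKHB2 fell 3.77-fold, ADAM19, a membrane-bound metalloprotease, 3.09-fold, and TFPI, the inhibitor of the tissue factor pathway of coagulation, 2.89-fold. The remaining 4 lay below the negative controls' 95th percentile on all 3 siERK3 arrays and have only bounds. GMFG was at least 2.10-fold, GEM, a small GTP-binding protein, at least 1.99-fold, ARL14EPL at least 1.81-fold and SERPIND1, a thrombin inhibitor, at least 1.32-fold lower. In limma these 20 genes had adjusted p from 0.00141 for MGP and PTX3 to 0.0373 for GMFG. Each kept its 3 siERK3 values clear of its 3 siCon values, which the naming rule required.

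**Figure D1:**
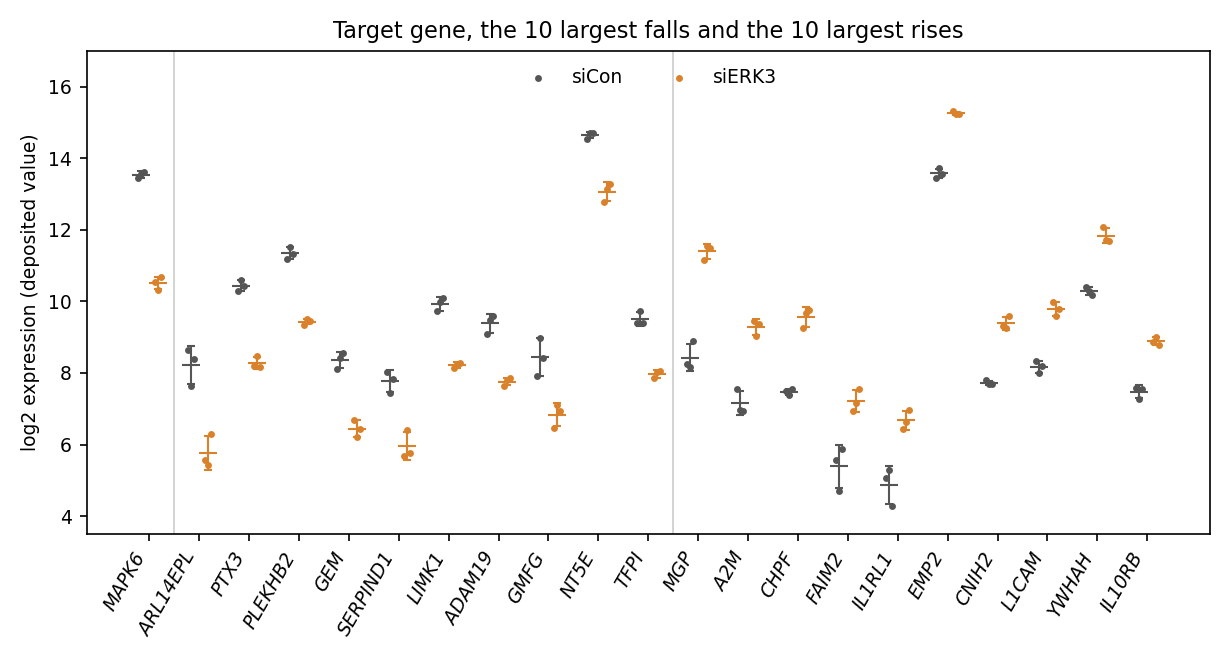
Log2 expression of MAPK6, the 10 largest falls and the 10 largest rises on each array (points), with the group mean and SD (bars; 3 arrays per group, siCon grey and siERK3 orange). MAPK6 lies near 13.54 in siCon and 10.51 in siERK3. For every gene shown the groups do not overlap, which the naming rule required of all but MAPK6.

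All 169 genes had a fitted change of at least 1.5-fold, and 34 of the higher and 48 of the lower genes reached 2-fold. Of the 169 genes, 17 lay below the negative controls' 95th percentile on all 3 arrays of both groups and 22 on all 3 arrays of 1 group; for 16 genes, some of them among these 22, only 1 or 2 arrays of a group lay above it. At an unadjusted p under 0.05, 1235 genes were higher and 1149 lower. In a fit of all probe sets 13.1% of the named ones and 12.4% of the negative controls reached that level. The other splits of the 6 arrays into 3 and 3 were examined after the results were seen. In them 10.5% to 14.9% of the negative controls reached it, so the controls' share is not tied to the groups. These shares exceed the 0.05 that the level allows, so limma's p can be too small at background level. That limits the calls of the 17 genes below the negative controls' 95th percentile in both groups. Among genes, 543 to 1049 reached an unadjusted p under 0.05 in those splits, against 2384 in the real one. The groups did not overlap for 19.8% of all genes, against 10% by chance and 8.99% of the negative controls. The number called rested on all 6 arrays, since the fit without siCon 1, siCon 2 or siCon 3 called 35, 60 or 28 genes, and without siERK3 1, siERK3 2 or siERK3 3 called 26, 25 or 23. With 1 array left out, 5 of the 20 largest changes lost their calls in 4 or 5 of the 6 fits. ARL14EPL was lost without siCon 1, siCon 3, siERK3 1 or siERK3 2 (highest adjusted p 0.0685 in limma), SERPIND1 without siCon 1, siCon 3, siERK3 1 or siERK3 3 (0.0764) and IL1RL1 without siCon 1, siERK3 1, siERK3 2 or siERK3 3 (0.104). GMFG passed only without siCon 1 and FAIM2 only without siCon 2 (highest adjusted p 0.136 for each), while MAPK6 and the other 15 of the largest changes passed in all 6 such fits. Of the 143 called genes outside the rule by which genes were named beforehand, which were examined in this way after their values were seen, 1 (IL6ST) passed in all 6 and 95 in 0.

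**Figure D2:**
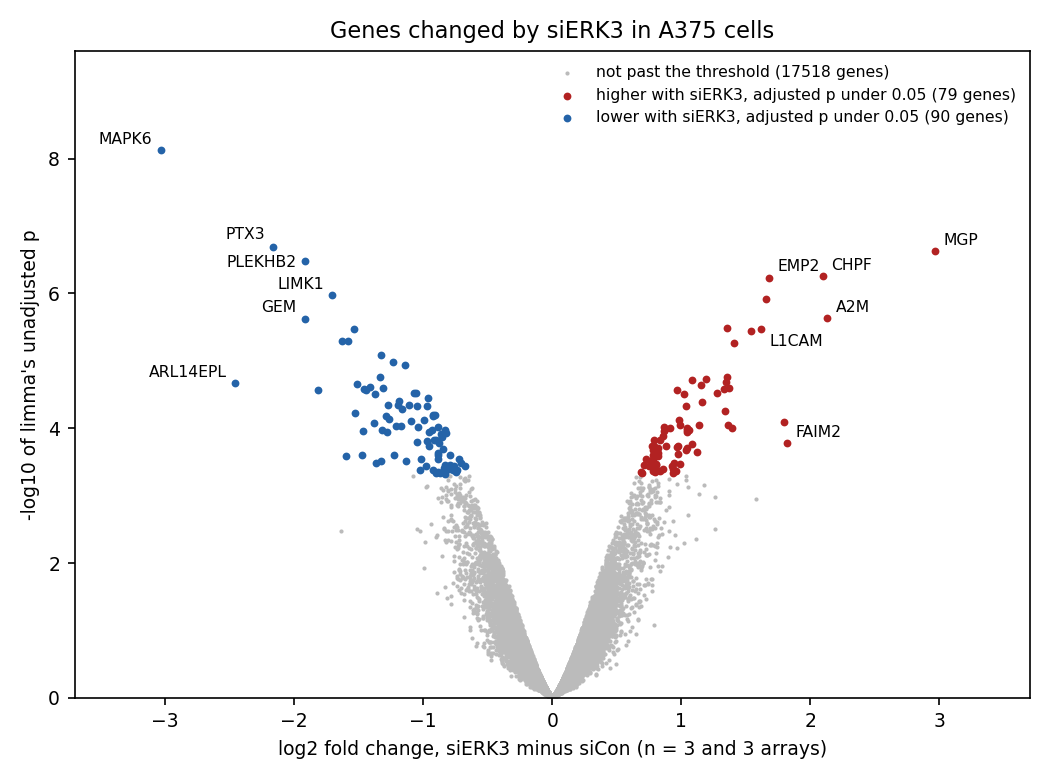
Log2 fold change of each gene, siERK3 minus siCon (horizontal axis), against -log10 of limma's unadjusted p (vertical axis), from 3 and 3 arrays. Red points are the 79 genes called higher, blue points the 90 called lower and grey points the genes not past the threshold, and MAPK6 at -3.03 has the smallest p.

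Of 33 gene lists fixed before the data were examined, 5 passed camera's test, 4 lower and 1 higher in siERK3, all at a preset correlation of 0.01 between genes. With an estimated correlation none of the 33 passed (smallest adjusted p 0.513, 3 at an unadjusted p under 0.05), nor did any with limma's fry (smallest adjusted p 0.0577), and with camera on ranks only the cytokine and the G2/M list passed. In each of the 5 lists the 3 siERK3 arrays' mean scores lay clear of the 3 siCon arrays' scores, where the exact permutation p of 0.1 is the smallest possible. Lists that camera did not call were split as cleanly, among them the YAP/TAZ targets, with scores of 0.08 to 0.10 in siCon and -0.15 to -0.04 in siERK3. A clean split therefore does not set the 5 lists apart.

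Secreted cytokines and targets of NF-kB, the inflammatory transcription factor, were the list with the largest mean change, -0.41 on the log2 scale over 27 measured genes. Over all genes tested, 5 members fell, 1 rose and 21 did not pass; adjusted over the list alone, 14 fell and 1 rose. IL1A, the alarmin interleukin 1 alpha, fell 2.36-fold from 12.21 to 10.97, IL24 fell 2.29-fold, and CCL2, a monocyte chemokine, fell 1.80-fold. CCL20, another chemokine, and IRAK2, an adaptor kinase of the IL-1 receptors, were each at least 2.19-fold lower, with all 3 siERK3 arrays below the negative controls' 95th percentile. Among members that passed only over the list alone were TNFAIP3 and NFKBIA, feedback inhibitors of NF-kB, with log2 changes of -0.81 and -0.49, ICAM1 with -0.82, CXCL1 with -0.74 and CXCL8 with -0.58. The member that rose, IL6, lay below the negative controls' 95th percentile in both groups, at 4.45 and 5.50. Camera gave the list an adjusted p of 4.79e-07, and an adjusted p = 0.513 with an estimated correlation. The calls of IL1A (lost without siERK3 1 or siERK3 3), CCL20 (without siCon 3, siERK3 1 or siERK3 3) and IRAK2 (without siCon 1, siCon 3, siERK3 1 or siERK3 3) had highest adjusted p of 0.0545, 0.0693 and 0.0687 in limma with 1 array left out. IL24 passed only without siCon 2 (highest adjusted p 0.0805), and CCL2 and IL6 in 0 of the 6 such fits (0.143 and 0.108). Leukocyte markers had a mean log2 change of -0.15 over 13 genes, and did not pass (adjusted p = 0.233 in limma's camera). Of these, 0 passed over all genes in limma (3 lower at an unadjusted p under 0.05) and 2 fell when adjusted over the list alone, LYZ at -0.85 and CD68 at -0.47, while the pan-leukocyte marker PTPRC lay at 4.03 in siCon and 4.19 in siERK3, below the negative controls' 95th percentile.

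Genes of the G2/M phase and mitosis had a mean log2 change of -0.19 over 40 measured genes, 34 of them lower and 6 higher. None passed limma's test over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 there were 9 lower and 2 higher. NUF2, a kinetochore component, had a log2 change of -0.65 (SE 0.14), BIRC5, which encodes survivin, of -0.57 (SE 0.15) and KIF20A, a mitotic kinesin, of 0.44 (SE 0.12). Camera gave an adjusted p of 0.000137, and an adjusted p = 0.646 with an estimated correlation. The list of G1/S and DNA replication genes had a mean log2 change of 0.00 over 35 genes. That mean hides a wide spread within siERK3, where the list scores were 0.20, -0.02 and -0.18 for siERK3 1, siERK3 2 and siERK3 3, against -0.07 to 0.05 in siCon. In this list 1 member rose, over all genes and adjusted over the list alone. It was CCNE2, which encodes a cyclin of S phase entry, by 0.76, with 1 of 3 siCon arrays above the negative controls' 95th percentile. CCNE2 passed in 0 of the 6 fits that left out 1 array (highest adjusted p 0.152 in limma).

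Transcriptional output genes of the classical ERK pathway had a mean log2 change of -0.18 over 24 measured genes. CCND1, which encodes cyclin D1, fell 1.67-fold over all genes tested and the other 23 did not pass; adjusted over the list alone, 5 fell and 1 rose. FOSL1, an AP-1 subunit, had a log2 change of -0.71, the feedback inhibitor SPRY2 of -0.53 and SPRED3, an inhibitor of the pathway, of 0.64, with 1 of 3 siCon arrays above the negative controls' 95th percentile. DUSP6, a phosphatase and a common readout of the pathway, had a log2 change of -0.13 (SE 0.12). Camera gave an adjusted p of 0.0136, and an adjusted p = 0.513 with an estimated correlation; the list's adjusted p was 0.0753 without siCon 3. CCND1 passed in none of the 6 fits that left out 1 array (highest adjusted p 0.166 in limma).

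Apoptosis regulators had a mean log2 change of -0.16 over 32 measured genes. TNFRSF10B, a death receptor for TRAIL, fell 1.81-fold over all genes and the other 31 did not pass; adjusted over the list alone, 4 fell and 0 rose. Of these 4, MCL1 (log2 change -0.65) and BIRC5 (-0.57) are known to oppose cell death and TNFRSF10B to promote it, and CASP10, at 6.41 and 5.74, lay below the negative controls' 95th percentile in both groups. Camera gave an adjusted p of 0.0284, and an adjusted p = 0.646 with an estimated correlation. The list's adjusted p was 0.120 without siCon 3, 0.0506 without siERK3 1, 0.256 without siERK3 3, 0.0645 among genes above the 30th percentile of mean level and 0.129 among those above the median, and TNFRSF10B passed in none of the 6 fits that left out 1 array (highest adjusted p 0.120 in limma).

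Sterol synthesis and uptake genes were the list called higher, with a mean log2 change of 0.16 and a median of 0.21 over 25 measured genes. None passed over all genes tested, where limma gave 8 higher and 3 lower at an unadjusted p under 0.05; adjusted over the list alone, 4 rose and 2 fell. DHCR7 (log2 change 0.70) and MSMO1 (0.61) are enzymes of cholesterol synthesis and FASN (0.65) is the fatty acid synthase. SREBF1 (0.64) encodes a transcriptional regulator of lipid synthesis. INSIG1, which retains that regulator in the endoplasmic reticulum, had a log2 change of -0.62 and HMGCS1, an early enzyme of the pathway, of -0.52. Camera gave an adjusted p of 0.0284, and an adjusted p = 0.513 with an estimated correlation; the list's adjusted p was 0.120 without siCon 3, 0.134 without siERK3 1 and 0.0645 among genes above the 30th percentile of mean level.

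**Figure D3:**
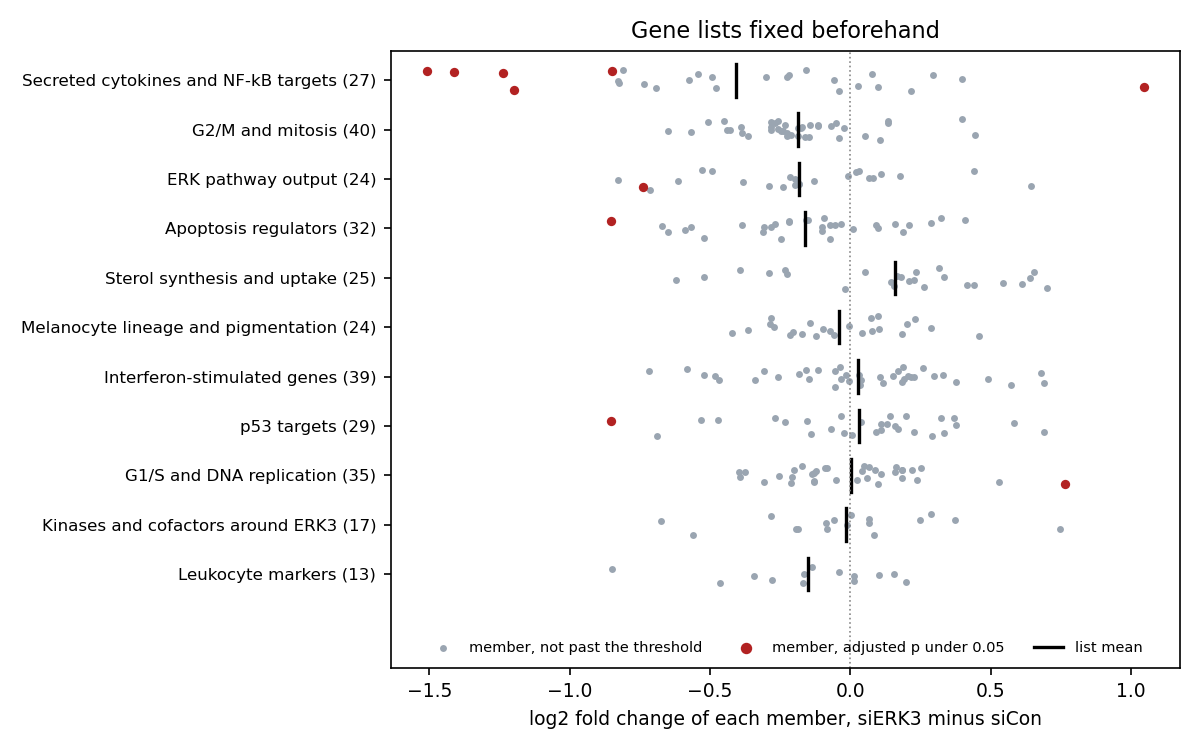
Log2 fold change of each measured member (points), siERK3 minus siCon, for the 5 lists called by camera and 6 others, with the number of measured genes in brackets. Black bars are list means, from -0.41 for secreted cytokines and NF-kB targets to 0.16 for sterol synthesis and uptake, and red points are members past the threshold over all genes.

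Lists tied to melanocyte identity and to responses to siRNA were not called. Melanocyte lineage genes had a mean log2 change of -0.04. Of 24, 0 passed in limma over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05). MITF had a change of -0.17 (SE 0.15) and SOX10 of -0.06 (SE 0.16). Pigmentation members such as MLANA, PMEL, TYR and TYRP1 lay below the negative controls' 95th percentile in both groups, at 3.65 to 4.39. A lower level of such members could not be seen. Interferon-stimulated genes had a mean of 0.03, with 0 of 39 passing in limma over all genes (10 at an unadjusted p under 0.05) and 1 higher and 1 lower adjusted over the list alone. For p53 targets the mean was 0.03, with 1 of 29 lower over all genes, TNFRSF10B, and 1 higher and 1 lower adjusted over the list alone. The 17 measured kinases and cofactors around ERK3 had a mean of -0.02 and none passed in limma over all genes, with 4 at an unadjusted p under 0.05. Adjusted over the list alone, 1 rose and 2 fell: MAPK3, which encodes ERK1, rose by 0.75 and MAP2K1, which encodes MEK1, fell by 0.68. The other, MAPK4, the closest relative of MAPK6, lay below the negative controls' 95th percentile in both groups, at 4.86 and 4.31. MAPKAPK5, the protein kinase known to bind ERK3, had a log2 change of -0.28 (SE 0.12; adjusted p = 0.363 in limma).

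Single members passed in lists that did not; apart from NT5E and L1CAM they were named after their values were seen. Of the YAP/TAZ targets (mean -0.18), NT5E and CCN1 fell, the latter by 1.13, and adjusted over the list alone 4 fell and 1 rose. In the extracellular matrix list (mean -0.05), the proteoglycan genes BGN and LUM went opposite ways, by 1.37 and -0.83, and adjusted over the list alone 3 rose and 4 fell. SMAD6, an inhibitor of BMP signalling, rose by 1.33 in the TGF-beta and BMP list (mean -0.06; 4 rose and 2 fell adjusted over the list alone). SLC7A11, the cystine transporter, fell by 1.45 in the ATF4 list (mean -0.05; 2 rose and 2 fell adjusted over the list alone). L1CAM was the member of the dedifferentiated and invasive melanoma list (mean 0.05) that passed over all genes; 2 rose and 2 fell adjusted over the list alone. Endothelial and keratinocyte markers (means -0.09 and 0.06) had 0 members above the negative controls' 95th percentile, and 0 passed in limma over all genes or adjusted over the list alone (0 and 1 at an unadjusted p under 0.05). Among fibroblast markers (mean 0.12), LUM fell over all genes, and 2 rose and 1 fell adjusted over the list alone. With 1 array left out, CCN1 passed only without siERK3 1 and LUM in 0 of 6 fits (highest adjusted p 0.154 and 0.157 in limma), and the calls of BGN (lost without siCon 1, siERK3 2 or siERK3 3), SMAD6 (without siERK3 1, siERK3 2 or siERK3 3) and SLC7A11 (without siCon 1, siCon 3 or siERK3 2) had highest adjusted p of 0.0724, 0.0764 and 0.0685.

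In 4 further lists 1 member each passed over all genes. The cell cycle repressor E2F7 fell by 0.88 among CDK inhibitors and senescence regulators (list mean -0.12), EDEM1, a factor of endoplasmic reticulum-associated degradation, fell by 1.32 in the unfolded protein response list (mean -0.08), and CIITA, the transactivator of MHC class II genes, rose by 0.99 in the antigen presentation list (mean 0.04). MMP13 fell in the list of matrix metalloproteases and plasminogen genes (mean 0.02), from 5.04 to 3.71, both below the negative controls' 95th percentile. Adjusted over the list alone, E2F7 and EDEM1 were again the calls of their lists, 2 rose and 1 fell for antigen presentation and 2 rose and 2 fell for the metalloproteases. With 1 array left out, EDEM1 passed only without siCon 2 and CIITA only without siCon 1 (highest adjusted p 0.108 and 0.111 in limma), and E2F7 and MMP13 in 0 of 6 fits (0.163 for each). The lists of hypoxia and glycolysis, heat shock, mitochondrial respiratory chain, ribosomal protein, DNA repair, Wnt, autophagy and lysosome, RNA interference and epithelial-mesenchymal transition genes had means between -0.06 and 0.04, with 0 members past limma's threshold over all genes and 0 to 7 per list at an unadjusted p under 0.05. Adjusted over the list alone, 2 fell in autophagy and lysosome, 1 rose in RNA interference and 0 passed in the other 7. Mean and median differed in sign for autophagy and lysosome, ATF4 targets, keratinocyte markers, epithelial-mesenchymal transition and RNA interference genes, and for G1/S and mitochondrial genes camera's direction was lower with means of 0.00.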

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

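The test of the probe sets outside the gene comparison was chosen after seeing the data. Of 3739 transcript clusters unnamed in the annotation used here, 8 passed limma's test in a fit of all probe sets of the table, 4 higher and 4 lower in siERK3. They drew attention because they lie outside the genes compared. The largest rise was 1.70 on the log2 scale (TC0900009950.hg.1) and the largest fall was -2.27 (TC1100013087.hg.1, adjusted p = 0.00389 in limma). At an unadjusted p under 0.05, 386 unnamed clusters (10.3%) passed. In the same limma fit 0 of 612 negative, 0 of 2197 positive and 0 of 94 spike-in or background controls passed, with 76 (12.4%), 162 (7.37%) and 0 at an unadjusted p under 0.05, against 13.1% of the named probe sets. The groups did not overlap for 8.99% of the negative controls, 16.2% of the positive controls, 15.3% of the unnamed clusters and 19.8% of the named probe sets. No explanation was tested.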

How the results depend on the processing

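All alternatives here were fixed before the data were examined. MAPK6 passed in all 17, with log2 changes from -3.11 to -2.94 and a highest adjusted p of 0.0350 in limma, without moderation of the variance. The 169 genes (79 higher, 90 lower, 169 at least 1.5-fold) became 365 (184, 181, 346) above the 30th percentile of mean level, 581 (281, 300, 392) above the median level and 70 (29, 41, 70) over all probe sets, where both the number of tests and the moderated variance change; the cause was not tested. With a mean-variance trend and robust eBayes 722 genes passed (343, 379, 439), all 169 among them, and without moderation 8 (4, 4, 4), 3 of them among the 169; the cause was not tested. With 1 array left out, and thus fewer samples, 23 to 60 genes passed (higher 9 to 30, lower 13 to 30, at least 1.5-fold 23 to 60), fewest without siERK3 3 and most without siCon 2. Quantile normalization (175), median subtraction (165), cyclic loess (176), the mean of probe sets (169) and array weights (218) stayed within 1.5 times the count, and all 169 genes kept their sign wherever they were tested. The 5 lists became 3 above the 30th percentile (apoptosis and sterol lost), 4 above the median (apoptosis lost), 0 with an estimated correlation, 0 with fry, 2 on ranks (ERK output, apoptosis and sterol lost), and 2 to 5 with 1 array left out (2 without siCon 3, with the same 3 lost, and 3 without siERK3 1, with apoptosis and sterol lost); the cause was not tested. Of the calls of the 25 called genes other than MAPK6 taken by the naming rule, 43 were lost with 1 array left out and 107 held, 35 were lost in other settings and 236 held, and 0 changed direction. For the 143 other called genes, examined after seeing the data, 778 calls were lost with 1 array left out and 80 held.

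With the replicate number as a block, 33 genes passed (11 higher, 22 lower, 33 at least 1.5-fold), all among the 169. The calls of 5 of the 26 called genes of the naming rule (CCND1, IL1RL1, IRAK2, SERPIND1 and TNFRSF10B) and of 131 of the 143 others ended. The numbers do not pair the arrays, since deviations from the group means of arrays with the same number correlated across genes at r = 0.05, -0.12 and -0.04, and not every array correlated best with its own number. The block changed no call of a list. Signal over background limits the 17 genes below the negative controls' 95th percentile in both groups.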

Other observations

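The genes grouped here, the matched random lists, the receptor list, the difference between the G1/S and G2/M lists, the splits and the fits of single genes outside the naming rule were chosen after the results were seen; the fits with 1 array left out and with an estimated correlation were fixed before the data were examined, and were set against an explanation only afterwards. Several genes of secreted, matrix and related cell-surface proteins passed limma's test without belonging to a list that did. IGFBP7, NID1 (a basement membrane protein), SERPINF1, SPP1 (osteopontin), CEMIP (which takes part in hyaluronan breakdown), CPA4 and APOE rose by 1.15, 1.03, 1.28, 1.04, 1.08, 1.35 and 1.34 on the log2 scale, while CEMIP2 and STC1 (a secreted glycoprotein) fell by 1.21 and 1.23. They were picked by hand, so their number in each direction is no result; among other genes of such proteins MGP, A2M and BGN rose and PTX3, TFPI, SERPIND1, ADAM19, LUM and MMP13 fell. Receptors also went both ways, with IL6ST, the shared signalling subunit of the IL-6 family, up by 1.36 (13.30 in siERK3, adjusted p = 0.00456 in limma), and TLR6, TNFRSF9 and IL7R down, with changes of -1.44, -0.97 and -0.87. The adhesion molecules ALCAM and NRCAM rose by 1.19 and 0.79, beside L1CAM. They too were picked by hand, and ICAM1 of the cytokine list had a change in the other direction. With 1 array left out IL6ST passed in all 6 limma fits. SERPINF1 passed only without siCon 1, siCon 2 or siERK3 1, CPA4 only without a siCon array, TLR6 only without siCon 1, siCon 2 or siERK3 2, IGFBP7 only without siCon 2 or siCon 3, CEMIP and ALCAM only without siCon 1 or siCon 2, APOE only without siERK3 1, CEMIP2 only without siCon 2 and STC1 only without siERK3 2, and NID1, SPP1, TNFRSF9, IL7R and NRCAM in 0 fits (highest adjusted p of these genes 0.166).

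Of genes tied to BMP and activin signalling, SMAD6 rose by 1.33, GDF11 by 0.78 and FST, which encodes follistatin, by 0.81. These 3 were picked by hand, so their shared direction is no result. Camera did not call the TGF-beta and BMP list, where limma gave 4 higher and 3 lower at an unadjusted p under 0.05. YAP1 fell by 0.84 and its target CCN1 fell by 1.13. This pair was picked by hand as well. Camera did not call the list of YAP/TAZ targets, where limma gave 2 higher and 4 lower at an unadjusted p under 0.05. Of the cell cycle genes, CACUL1 fell by 0.93. FAM72A, FAM72B, FAM72C and FAM72D, near-identical paralogs, had changes between -0.97 and -0.71; which of them differed is uncertain, since probes can be shared between them. With 1 array left out SMAD6 passed only without a siCon array, CCN1 only without siERK3 1 and CACUL1 only without siCon 2, and GDF11, FST, YAP1 and the 4 FAM72 genes in 0 of 6 limma fits (highest adjusted p of these genes 0.173). No enrichment of these hand-picked groups was tested.

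The lower level of secreted cytokines and NF-kB targets, -0.41 on average over 27 genes, was weighed first. Of 10000 random lists matched on mean level none had a mean as low (share 1e-04, the smallest possible), which argues against a shift of all genes at that level. With 1 array left out camera's adjusted p was at most 2.96e-05, which argues against 1 array alone only at the preset correlation. Drift of co-regulated genes between cultures stays open, since the adjusted p was 0.513 with an estimated correlation, although the arrays' list scores changed by -4.90 pooled within-group SDs. Receptors and adaptors of the IL-1 and Toll-like pathway had a mean log2 change of 0.082 over 28 genes, within the range of matched random lists (-0.11 to 0.11), with 18 higher, 10 lower, IL1RL1 (below the negative controls' 95th percentile on all 6 arrays) called higher and TLR6 lower. That list leaves out the members of the cytokine list, and with 1 of them, IRAK2, at least 2.19-fold lower, its mean was 0.03 over 29 genes, so a lower input through them cannot be told apart from an unchanged one. The biological explanation the design gives, the loss of ERK3, stays open too, and was not tested apart from effects of the siRNA on other transcripts.

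The lower level of G2/M and mitosis genes, -0.19 over 40 genes with 34 lower, was weighed in the same way. A mean as low was rare among the matched lists (share 3e-04), which argues against a shift of genes at that level. Camera's adjusted p was at most 0.00658 with 1 array left out, which argues against 1 array alone only at the preset correlation. The arrays' list scores were 0.14 for siCon 1 and siCon 3, -0.004 for siCon 2 and -0.05 to -0.13 for siERK3. Thus siCon 2 lay nearer to siERK3 1 than to the other siCon arrays. Drift between cultures stays open, with an adjusted p = 0.646 with an estimated correlation and list scores that changed by -2.88 pooled SDs. Fewer cycling cells overall would lower the G1/S list as well, but the difference between the G1/S and G2/M changes was 0.19 (SE 0.09, 95% interval -0.06 to 0.44), so the candidate explanation cannot be told apart from a change in G2/M genes alone.

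The number of genes was compared over the 10 splits of the 6 arrays into 3 and 3. The real split gave 169 genes, all at least 1.5-fold, and the highest other split 0 on both counts in limma. At an unadjusted p under 0.05 the real split gave 2384 genes against 543 to 1049. Camera called 5 lists in the real split and 0 to 3 in the others. Only the split of siCon 1, siERK3 2 and siERK3 3 from the rest called 0, so scrambled groups gave list calls too. In each case 1 of the 10 splits, the real one, gave a result as large, and 10 splits are too few for a share under 0.05. The groups did not overlap for 19.8% of the named probe sets in the real split and for 7.47% to 11.8% in the others. For the negative controls the real split gave 8.99%, within the range of 8.17% to 11.3% of the others, and 12.4% at an unadjusted p under 0.05, within 10.5% to 14.9%, so an excess of such p-values among them is not tied to the groups.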
